A study of Arabidopsis thaliana with 4 samples.

How the data were processed

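Small RNA libraries from Arabidopsis leaf were sequenced in 4 libraries, of which 2 carried the label RecJ, an exonuclease, and 2 the label SS, for the reverse transcriptase Superscript II. Both groups used high definition adapters, which carry random bases at the ligated ends, and the labels did not state which reverse transcriptase was used in the RecJ libraries or whether the SS libraries were treated with the exonuclease. The labels give replicate numbers but do not say whether libraries came from separate plants. The p-values of the group comparisons therefore measure only the spread between libraries. The count tests pool this spread over features, for miRNAs almost wholly. The permutation p-values for GC content and folding came from shuffling features and do not measure that spread.

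The deposited files hold raw read counts: per the values, the authors listed each distinct sequence once, joined by a hyphen to its count, in a unit other than a plain count column. All lines could be read, no sequence was repeated within a library or held an N, and lengths ran from 17 to 34 nt. Trimming and filtering were not stated, and the submitters' processing notes name only the TAIR10 genome build. Total reads were 12955771 and 12184420 in RecJ replicates 1 and 2, and 20667271 and 14574347 in SS replicates 1 and 2. Intervals on shares of a library are 95% Wilson intervals and floors are 3 counts. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Every pair of libraries differed beyond sampling noise, with chi-square per degree of freedom from 44.6 to 450.

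Sequences were placed with 0 mismatches on a RefSeq release of the TAIR10 assembly, whose nuclear chromosomes, plastid and mitochondrion were all searched. The files carry no coordinates, so their build was not compared with it. Each sequence received 1 class in a fixed order: rRNA, tRNA, snRNA or snoRNA, miRNA locus, TAS locus, pseudogene, protein coding gene, other gene, no annotated gene, and no match. The 4000 nt downstream of the 5.8S rRNA genes were counted as rRNA because the 25S genes are not annotated. Reads from other nuclear rRNA repeats missing from the annotation could fall into other classes. The rRNA, tRNA, snRNA or snoRNA and miRNA locus classes took only reads on the strand of the gene. Reads matching only the opposite strand of such genes fell into other classes. No transposon annotation was used. Mature miRNAs were the distinct mature sequences of the annotation, and 52 of 53 well-known sequences written down beforehand were found among them. A miRNA's guide strand was the annotated arm with at least 15 bases identical to the family's known guide. Reads of 18 to 30 nt were used except where stated.

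The tests, filters, lists and rule for named features were chosen before the data were examined, with the exceptions given here. The planned quasi-likelihood count test was replaced by limma-voom (limma 3.58.1, R 4.3.3), because the cells of the files join each count to its sequence and were recorded as a unit other than counts. The counts could be read from these cells, so the format itself did not prevent the planned test. TMM factors were computed with a trim of 0.3 on ratios and 0.05 on levels. Features needed 10 or more reads in at least 2 libraries. The model held the group alone, with SS minus RecJ as the direction, and Benjamini-Hochberg adjustment with a threshold of 0.05 was applied over 183 mature miRNAs, 9232 loci and 115427 distinct sequences. The moderated variances drew on 242 prior degrees of freedom for miRNAs, 3.47 for loci and 12.7 for sequences, beside 2 residual degrees of freedom. For miRNAs the SE and p-values therefore rest almost wholly on the pooled spread, not on that of each miRNA's own libraries. At loci, a sequence with several genomic positions added an equal part of its reads to each. Levels are reads per 1000000 (RPM), scaled with the TMM factors, given with their SD.

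Named were the most read guide of 28 families, up to 10 called miRNAs in each direction that moved alike in all 4 SS and RecJ library pairs, the 5 loci and 5 sequences of largest change in each direction, the 5 most read miRNAs, the 3 most read sequences and the TAS loci. The 11 miRNA lists covered conserved families, Brassicaceae families, flower or pollen miRNAs, nutrient-responsive families, triggers of secondary siRNAs, passenger strands, 22-nt miRNAs, and miRNAs starting with U, A, C or G. They were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Shares of reads were compared with a two-sided exact permutation test, for which 2 against 2 libraries give 3 distinct splits and a smallest p of 0.333. Correlations with GC content used 100000 permutations. Tests on tRNA reads took reads equal to a tRNA gene with at most 1 changed base or added CCA bases. Self-folding was predicted with ViennaRNA 2.7.2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 were used.

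The count tests were tested on simulated data, in which features of similar read number shared the median dispersion found in these libraries. The simulation held no difference in dispersion between such features and no effect of the replicate number. Recovery in the real data may therefore be lower, and false calls more frequent. Among miRNAs, 85% of 2-fold and 100% of 4-fold changes were recovered, and 7.5% of calls were false. For loci the shares recovered were 73.6% and 100%, with 5.81% of calls false. For sequences they were 12.9% and 70.1%, with 7.14% of calls false. Alternatives covered the scaling, the filter, a minimum fold, reads with moved ends, family sums, reads with a single genomic position, single lengths, distinct sequences in place of reads, the replicate number as a block and leaving out each library. limma-trend was added after the data were seen.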

Results

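Small RNAs of 17 to 34 nt were counted in 4 leaf libraries of Arabidopsis, 2 labelled RecJ and 2 labelled SS. RecJ is an exonuclease that degrades single-stranded DNA, and SS stands for Superscript II, a reverse transcriptase. Libraries held between 12184420 and 20667271 reads and between 2935118 and 4185761 distinct sequences, of which 73.9% to 75.1% were read once. The comparison asked how the small RNAs recovered differ between the 2 ways of making a library. The labels name neither group as a control and do not say whether the SS libraries were also treated with the exonuclease, and each difference is given as SS relative to RecJ.

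Among mature miRNAs that differed, miR393a-5p and miR160a-5p changed most. Reads of miR393a-5p (chromosome 2, 16652111 to 16652132), which targets auxin receptors, were 134 ± 62.0 per 1000000 reads (RPM) in RecJ and 25.4 ± 3.61 in SS (mean ± SD, n = 2 each), a log2 change of -2.32 ± 0.21 (SE). Reads of miR160a-5p (chromosome 2, 16340282 to 16340302), which targets auxin response factors, were 232 ± 51.7 and 55.8 ± 4.46 RPM, a log2 change of -2.03 ± 0.18. The related miR166a-3p and miR165a-3p, which target leaf polarity genes, fell from 6287 ± 314 to 3026 ± 153 and from 881 ± 14.1 to 512 ± 67.7 RPM. Reads of miR396a-3p rose from 2675 ± 411 to 4088 ± 136 RPM, a log2 change of 0.62 ± 0.15.

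Of 183 mature miRNAs tested with limma-voom, 15 passed an adjusted p of 0.05, 4 higher and 11 lower in SS, and 38 had an unadjusted p under 0.05. All 15 moved alike in 4 of 4 library pairs. Adjusted p was 3.57e-21 for miR393a-5p, 2.99e-21 for miR160a-5p, 3.34e-10 for miR166a-3p, 5.25e-05 for miR165a-3p and 0.00105 for miR396a-3p. These values rest on the spread pooled over miRNAs. Reads of miR393a-5p alone were 178 and 90.3 RPM in RecJ replicates 1 and 2. The other miRNAs that fell were miR773a (log2 change -1.40), miR171b-3p (-1.25), which targets GRAS transcription factors, miR167d (-0.74), miR319a (-0.67), miR164c-5p (-0.65), miR161.1 (-0.53) and miR390a-5p (-0.51). Those that rose were miR5026 (0.57), miR157a-5p (0.54) and miR824-5p (0.45). Summed over all sequences of a family, the log2 change was -0.39 for miR171, -0.53 for miR393, -0.26 for miR164 and 0.11 for miR167. Of these sums only that of miR393 was called. The sums were -1.25 for miR160, -0.92 for miR166, -0.72 for miR165, -0.59 for miR319, -1.39 for miR773, -0.48 for miR161 and -0.48 for miR390. With median-of-ratios size factors 8 miRNAs were called, 1 higher and 7 lower, and with total reads as the only scaling 11 were called, 4 higher and 7 lower. Total-read scaling moved the median log2 change of all miRNAs from -0.00 to 0.13. Without RecJ replicate 2, only miR160a-5p and miR393a-5p were called, 2 in all.

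**Figure D1:**
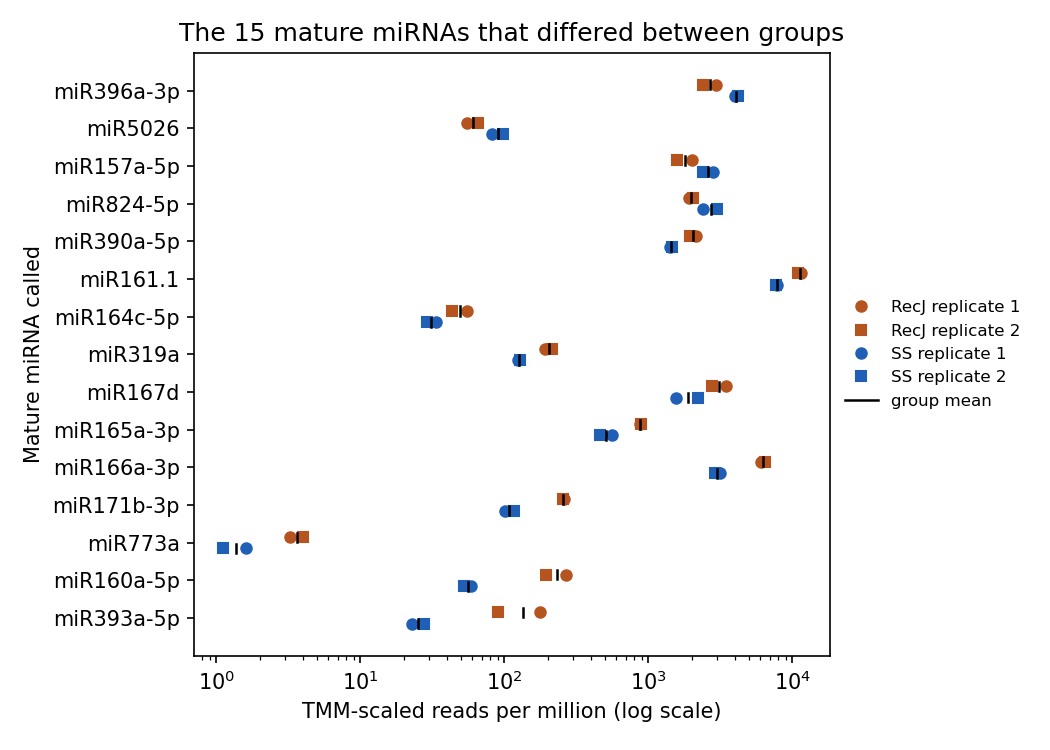
RPM after TMM scaling (log axis) of the 15 mature miRNAs called, with a point for each of the 4 libraries and a black bar at each group mean. The widest gaps are those of miR393a-5p (134 against 25.4) and miR160a-5p (232 against 55.8).

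Of the 5 most read miRNAs, only miR161.1 was called. Reads of miR167a-5p (chromosome 3, 8108090 to 8108110) were 25035 ± 625 RPM in RecJ and 28341 ± 3970 in SS, and those of miR158a-3p were 9832 ± 578 and 10862 ± 625. Reads of miR161.1 fell from 11243 ± 353 to 7787 ± 93.6 RPM (n = 2 each, limma adjusted p = 0.00482). With reads whose ends lay within 2 nt added, its log2 change was -0.20 and that of miR773a -0.26, and neither was called. With these reads, 8 of the 15 miRNAs were no longer called, the others being miR157a-5p (log2 change 0.44), miR164c-5p (-0.63), miR319a (-0.49), miR390a-5p (-0.51), miR824-5p (0.45) and miR5026 (0.59). For miR159b-3p the levels were 7347 ± 149 and 8870 ± 735 RPM, and for miR159a, its close relative, 7439 ± 560 and 8081 ± 1326. Of the 28 families whose most read guide strand was tested, 8 guides were lower, 1 was higher and 19 were not called. Among the latter were miR168a-5p, which targets ARGONAUTE1, at 4382 ± 281 and 4439 ± 739 RPM, and miR398b-3p at 1621 ± 17.6 and 1714 ± 51.4.

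Among 43 guides of families conserved among land plants, 1 was higher, 9 were lower and 33 were not called, with the same counts adjusted over the list alone and a median log2 change of -0.11. The camera adjusted p of this list was 0.00628 at the preset correlation but 0.434 with an estimated correlation. Among 7 triggers of secondary siRNAs, 3 were lower, 3 adjusted over the list alone, with a median of -0.51. Their camera adjusted p was 0.00628 at the preset correlation but also 0.434 with an estimated correlation. The members called were miR393a-5p, miR161.1 and miR390a-5p, which directs cleavage of TAS3 transcripts, while miR173-5p, the trigger of TAS1 and TAS2, was at 66.6 ± 3.93 and 57.6 ± 3.37 RPM.

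The other 9 lists did not pass camera. For Brassicaceae families 1 of 46 members was higher and 2 were lower (adjusted p = 0.359), and the counts adjusted over the list alone were the same. For nutrient-responsive families 0 of 11 were called, also adjusted over the list alone (adjusted p = 0.872); miR395b, which responds to sulfate supply, was at 11.99 ± 1.64 and 8.45 ± 1.77 RPM. For flower or pollen miRNAs 1 of 6 was lower, miR167d, and 1 adjusted over the list alone (adjusted p = 0.946), with a median of 0.03 and a mean of -0.00. For passenger strands 1 of 43 was higher, 1 adjusted over the list alone (adjusted p = 0.683), with a median of 0.02, a mean of -0.03 and camera pointing up. For 22-nt miRNAs 2 of 21 were lower, 2 adjusted over the list alone (adjusted p = 0.296). Among miRNAs starting with U, 2 were higher and 10 lower of 109, with equal counts adjusted over the list alone (adjusted p = 0.609). Among those starting with A, 1 was higher and 1 lower of 35, which became 0 and 1 adjusted over the list alone (adjusted p = 0.522). Of those starting with C, 0 of 21 were called, 0 adjusted over the list alone, with a median of 0.03, a mean of -0.05 and an adjusted p of 0.946. Of those starting with G, 1 of 18 was higher, and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.946).

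The loci called were 11 of 66 tRNA-Ser genes tested, MIR160a and 4 of 7 MIR166 genes, all lower in SS. Of 9232 annotated loci, 16 passed limma-voom, 0 higher and 16 lower, with 661 at an unadjusted p under 0.05. Reads at MIR160a (AT2G39175, chromosome 2, 16340279 to 16340363) fell from 82.8 ± 16.2 to 25.3 ± 0.945 RPM (n = 2 each, limma adjusted p = 0.0376), a log2 change of -1.69 ± 0.14. The other loci of largest change were the tRNA-Ser genes AT3G09595 (-1.62), AT4G25585 (-1.62), AT1G55625 (-1.62) and AT5G02725 (-1.62), each lower in 4 of 4 pairs. AT3G09595 was at 65.8 ± 8.999 and 21.4 ± 1.95 RPM. The called tRNA-Ser genes share most of their reads, and MIR166c, MIR166d, MIR166f and MIR166g, with log2 changes of -0.95 to -0.96, also share reads. None was called without SS replicate 1 or without SS replicate 2, or with a minimum of 100 reads (0 each), 100 loci were called without RecJ replicate 2, and total-read scaling gave 22 higher and 96 lower. From reads with a single genomic position 6 other loci were higher and 5 lower.

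TAS loci, which give rise to trans-acting siRNAs, were not called. Reads at TAS3 were 1811 ± 132 RPM in RecJ and 1636 ± 123 in SS (log2 change -0.14 ± 0.10). For TAS2 the values were 4838 ± 200 and 5252 ± 209, and for TAS1C 5581 ± 70.0 and 5894 ± 409. TAS1A was at 3437 ± 400 and 3764 ± 553, TAS1B at 1012 ± 12.3 and 1084 ± 48.8, and TAS4 (AT3G25795) at 13.8 ± 3.38 and 14.9 ± 1.36 RPM. The log2 changes of these 5 loci ranged from 0.08 to 0.13.

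Fragments of tRNA with a changed base were the largest group among single sequences that differed. Of 115427 distinct sequences, 311 passed limma-voom, 35 higher and 276 lower in SS, with 12006 at an unadjusted p under 0.05. The majority direction turned over when a RecJ library was left out, to 602 higher and 478 lower without RecJ replicate 1 and 614 higher and 214 lower without RecJ replicate 2, and no sequence was called without SS replicate 1 (0). Of the 311 calls, 7 higher and 71 lower were tRNA sequences with 1 changed base, 2 and 52 were exact tRNA sequences, 3 and 37 came from rRNA and 3 and 10 from miRNA loci. The largest increases were of a 30-nt fragment from the 5′ end of tRNA-Gly with the change G9A, counted from the first base of the tRNA, whose reads rose from 1.86 ± 0.452 to 20.7 ± 6.69 RPM (n = 2 each, limma adjusted p = 0.000189, log2 change 3.43 ± 0.32), and of the same fragment with G9T (log2 change 3.19 ± 0.62). They were followed by 3 overlapping 24-nt sequences with log2 changes of 3.05, 2.98 and 2.78, each with more than 100 genomic positions. Among these positions was AT3G00670 on chromosome 3 from 14213185 to 14213214. The class of these 3 sequences was other gene. Whether they come from rRNA repeats, missing from the annotation or read on the opposite strand, was not tested.

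The 5 sequences of largest decrease had no exact match in the genome and were 22 to 26 nt long. All 5 ended in at least 14 bases equal to the 3′ end of a tRNA with CCA, and their other bases were not traced. Such an end was found in 7 of the 37 sequences without a genomic match that were called lower (18.9%) and in 0.672% of those not called. The 7 include these same 5 sequences, so the 18.9% is largely the same observation. Of the 5 sequences of largest decrease, 4 were absent from both SS libraries and at least 82.7-fold, 59.8-fold, 42.4-fold and 33.8-fold lower, relative to total reads and against a floor of 3 counts per library. The fifth had 167 and 244 reads in RecJ and 1 and 0 in SS, a ratio with a counting interval of 103 to 22811. The most read sequence was the 22-nt AGTTACTAATTCATGATCTGGC, at 2 plastid positions outside annotated genes (141473 to 141494 is 1 of them), with 25978 ± 1294 RPM in RecJ and 30489 ± 636 in SS, and was not called. The next most read were miR167a-5p and miR158a-3p. Without SS replicate 2, 193 sequences were higher and 281 lower, while a minimum of 100 reads gave 5 higher and 74 lower.

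Both groups showed the 21-nt and 24-nt peaks of plant small RNAs, the first rich in miRNAs and the second in siRNAs of repeats. Reads of 21 nt made up 18.8% ± 0.815 of 18 to 30 nt reads in RecJ and 20.1% ± 0.290 in SS (n = 2 each, exact permutation p = 0.333), a difference of 1.28 points that exceeded the spread within either group. The difference was 0.704 points without RecJ replicate 1. Among distinct sequences it was 0.329 points, with overlap between groups. Reads of 24 nt made up 31.5% ± 0.0615 and 31.9% ± 1.43 (exact p = 1), a difference within the spread of SS. Reads of 25 nt were 3.59% ± 0.0613 and 3.18% ± 0.109, with no overlap between groups. As shares of all reads of 17 to 34 nt, however, the groups overlapped at both 21 nt (16.9% ± 1.96 and 18.2% ± 0.889) and 25 nt (3.21% ± 0.290 and 2.88% ± 0.197). Chance alone separates 2 libraries from 2 with a probability of 0.333, the smallest p that the design allows, so no share could pass 0.05.

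**Figure D2:**
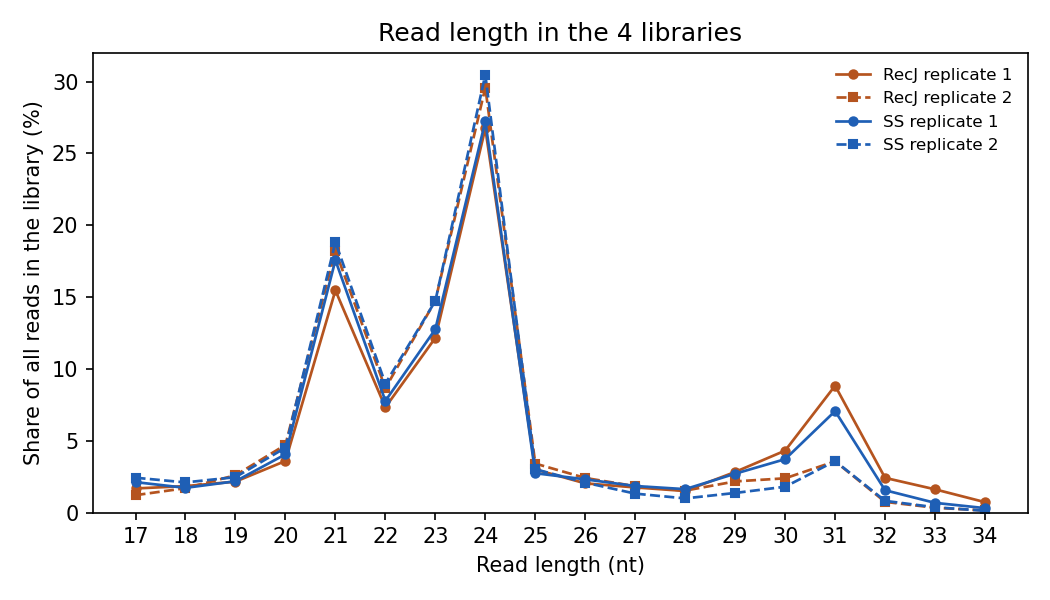
Share of all reads in a library (percent) by read length from 17 to 34 nt, with a line for each of the 4 libraries. All have peaks at 21 and 24 nt, and replicate 1 of each group has the higher share at 29 to 34 nt, 20.7% and 16.0% against 9.35% and 8.06%.

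Reads from miRNA loci were 14.9% ± 0.230 of 18 to 30 nt reads in RecJ and 15.9% ± 0.0508 in SS (n = 2 each, exact permutation p = 0.333), with no overlap between groups. The groups overlapped in rRNA (14.4% ± 1.68 and 13.1% ± 0.483) and tRNA (7.47% ± 1.85 and 6.80% ± 1.73). Between libraries of the same number, tRNA was lower in SS for replicates 1 (8.78% and 8.02%) and replicates 2 (6.17% and 5.57%), while rRNA was 13.3% and 13.4%, and 15.6% and 12.7%. Reads with no exact genomic match were 12.2% ± 0.329 and 11.7% ± 0.0209, and plastid reads 11.9% ± 0.0368 and 13.0% ± 0.816, both without overlap. The remaining classes overlapped between groups: snRNA or snoRNA (0.227% ± 0.0135 and 0.255% ± 0.0345), TAS loci (1.87% ± 0.141 and 1.99% ± 0.255), pseudogenes (7.12% ± 0.132 and 7.23% ± 0.386), protein coding genes (8.79% ± 0.103 and 9.03% ± 0.392), other genes (1.87% ± 0.0407 and 1.92% ± 0.0949) and positions outside annotated genes (31.2% ± 0.1304 and 32.1% ± 1.19).

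The first base, which sorts small RNAs between ARGONAUTE proteins, was U in 65.3% ± 0.820 and 65.7% ± 1.69 of 21-nt reads and A in 56.7% ± 0.447 and 57.0% ± 0.371 of 24-nt reads, in each case with overlap between groups. At 22 nt, A was first in 49.6% ± 1.13 of RecJ and 53.3% ± 0.762 of SS reads (n = 2 each, exact permutation p = 0.333). The most read sequence alone made up 32.3% ± 2.11 and 36.9% ± 1.28 of 22-nt reads, and without it A was first in 25.6% ± 0.652 and 26.01% ± 0.292. At 24 nt, G ended 20.6% ± 0.146 of RecJ and 23.7% ± 0.361 of SS reads, and U ended 34.6% ± 0.0556 and 31.4% ± 0.421. At 21 nt, C ended 16.0% ± 0.235 and 13.7% ± 0.0200 of reads, and 19.98% ± 0.271 and 19.5% ± 0.384 of reads outside miRNA loci.

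At an equal 12184420 reads, RecJ and SS libraries held 2923826 ± 171373 and 2923631 ± 145642 distinct sequences, a difference of -0.00666% (exact permutation p = 1, n = 2 each). The difference was -3.99% without RecJ replicate 1, 4.32% without RecJ replicate 2, 3.52% without SS replicate 1 and -3.53% without SS replicate 2. Across 183 miRNAs, which are not independent replicates, Pearson's r of log2 RPM with a pseudocount of 1 was 0.996 on average within groups and 0.991 to 0.993 between them, and Spearman's rho averaged 0.987 and 0.984, although the pair of RecJ replicate 1 and SS replicate 1 (0.987) lay above the pair of SS libraries (0.985). The median absolute log2 difference averaged 0.19 over the 2 pairs within groups and 0.28 over the 4 pairs between them, a ratio of 1.44. For distinct sequences the averages were 0.21 and 0.25, a ratio of 1.18, but RecJ replicate 1 differed less from SS replicate 1 (0.22) than from RecJ replicate 2 (0.24).

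GC-rich miRNAs and sequences tended to be lower in SS, weakly. Across the 183 miRNAs, Pearson's r between GC content and log2 change was -0.185 (permutation p = 0.0117, adjusted 0.0156) and Spearman's rho -0.138 (permutation p = 0.0635, adjusted 0.0635). Across 115427 sequences they were -0.114 and -0.111, both at the smallest p that the permutations can give (1e-05, adjusted 2e-05). Features are not independent replicates, and 4 relations were computed in this family. Without SS replicate 2 Spearman's rho for miRNAs was -0.0688, without SS replicate 1 it was -0.231, and for sequences without RecJ replicate 2 it was -0.0424.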

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

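The tests of moved ends, tRNA content, amount of tRNA fragments and reverse transcription of a modified base were chosen only after related values had been seen. The labels name no biological difference between the groups and do not say whether libraries came from separate plants, and no biological explanation was tested.

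Reads of 29 to 34 nt, mostly outside the 18 to 30 nt range of the comparisons, made up 20.7% of RecJ replicate 1 and 16.0% of SS replicate 1, but 9.35% and 8.06% of replicates 2. A higher tRNA content of replicate 1 at all lengths is argued against. Among 20 to 26 nt reads the share of tRNA in replicate 1 was only 1.01 times that in replicate 2 for RecJ and 1.04 times for SS. This window could not show a rise limited to longer tRNA fragments. Among 29 to 34 nt reads, tRNA made up 55.4% and 51.9% in RecJ replicates 1 and 2, and 58.3% and 55.0% in SS replicates 1 and 2. A candidate explanation is a wider size selection in replicate 1 of both groups. Outside tRNA genes, the share of 29 to 34 nt reads was also higher in replicate 1, by 2.06 times in RecJ and 1.96 times in SS. Other steps shared by libraries of the same number were not tested, and stay open.

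Reads of 17 nt, left out of the comparisons, made up on average 1.45% of RecJ and 2.27% of SS reads.

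Reads without an exact genomic match that equalled a tRNA with CCA or 1 changed base made up on average 2.15% ± 0.967 of RecJ and 1.27% ± 0.395 of SS reads, with overlap between the groups (2.83% and 1.46% in RecJ, 1.55% and 0.993% in SS). They include a pattern at the A of the T loop, 15 bases before the last base of the tRNA gene: A was read as G in 31.6% ± 4.16 of reads covering it in RecJ and 10.7% ± 0.462 in SS, and as T in 61.7% ± 3.29 and 79.2% ± 0.388 (n = 2 each), over 13 tRNA types with 1000 or more changed reads there. Over every tRNA, G made up 21.9% ± 4.16 and 6.79% ± 0.178, and T 42.7% ± 0.155 and 50.6% ± 0.605. These percentages count reads exact over this base or with another base there. They pool tRNA types whose mix may differ between groups. By type, the mean percentage read as T was lower in SS for tRNA-Asp, tRNA-Leu, tRNA-Ser and tRNA-Val, and higher for the other types. A general rate of sequencing or PCR errors is argued against, since A read as G at other A positions of the same tRNAs had a group ratio of 0.893, against 0.337 at the T loop. The share of G among changed reads had a median ratio of 0.533 over the 13 tRNA types and was lower in both SS libraries for 12 of them, a share of 0.923, with tRNA-Leu as the exception. This share does not depend on the amount of tRNA fragments. For 7 of the 13 types its ratio lay outside the bounds set for an alike share, and for the other 6 it lay inside. The 7 types are set apart only by the same share that makes the pattern. Over the 13 types this split could not decide whether a differing amount was the cause. The same values restate the pattern, so they cannot test the reverse transcription of a modified base, which stays open.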

How the results depend on the processing

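The limma-trend setting was chosen only after the data were seen; the DESeq2 alternative was not run. Of the 180 values that the alternatives gave for the 15 called miRNAs, 0 were reversed in direction. Of these values, 108 stayed on their side of the threshold and 72 did not. Family sums entered for only 1 of the 15, and a minimum of 100 reads did not cover all of them. The minimum fold reused the main fit, so its direction could not change. For miR167d (log2 change -0.74) the sum over the miR167 family was 0.11. Leaving out a library leaves a lone library, assumed to vary like the other group. The count of miRNAs was 15 and became 8 with median-of-ratios factors, 6 with the lowest filter, 7 with a minimum of 100 reads, 5 with a log2 change over 1, 9 with family sums, 35 with the replicate number as a block (correlation of deviations 0.355), miR159b-3p and miR156a-5p among them, and 2 to 13 without single libraries. The count of lists was 2 and became 0 with an estimated correlation and 0 with fry. The count of loci was 16 and became 118 with total reads, 79 with the lowest filter, 0 with a minimum of 100 reads, 37 with 24-nt reads, 72 with the block (0.0606) and 0 to 100 without single libraries. With reads at a single genomic position 11 loci were called, 6 higher and 5 lower, and 0 of them were among the 16. The count of sequences was 311 and became 536 with total reads, 32 with the lowest filter (23 higher, 9 lower), 79 with a minimum of 100 reads, 1707 with the block (0.0784) and 0 to 1080 without single libraries. Differences in points moved with distinct sequences to 0.329 for 21 nt, -0.0192 for miRNA loci and -0.490 for first A at 24 nt, and to 0.745 for miRNA loci at 21 to 24 nt. Spearman's rho with GC moved for miRNAs to -0.279 with a minimum of 100 reads, -0.0835 at 21 nt, -0.452 at 22 nt and -0.231 to -0.0688 without single libraries, and for sequences to -0.172 at 21 nt, -0.181 at 22 nt, -0.0456 at 24 nt and -0.131 to -0.0424 without single libraries. A minimum fold and family sums test fewer or stricter items by construction; for the others the cause was not tested. At the depth of these libraries 12.9% of simulated 2-fold changes in sequences were found, against 85% in miRNAs; what limits them was not tested.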

Other observations

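The test of moved ends, the comparison of folding among called miRNAs and the values at single tRNA positions were chosen only after the results were seen.

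Several tRNAs differed at positions where reads depart from the gene. Each percentage at a position counts only reads with the named change and reads exact over it, so reads with another change there are left out. In nuclear tRNA-Gln the base T at position 20 was missing from 35.7% ± 6.69 of these reads in RecJ and 18.3% ± 1.15 in SS (n = 2 each, positions counted from the first base of the tRNA). In tRNA-Asn the change G25T was present in 72.8% ± 1.12 and 55.5% ± 3.80, and in tRNA-Gly G9A in 0.584% ± 0.133 and 1.75% ± 0.284. Reads of tRNA ending in added CCA bases were 2655 ± 949 per 1000000 reads in RecJ and 1277 ± 166.6 in SS, beside 119149 ± 46524 and 112120 ± 35902 for exact tRNA reads. By class, the median log2 change of loci was -0.29 for 16 rRNA genes, 0.26 for 247 snRNA or snoRNA genes and -0.12 for 649 tRNA genes.

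The 11 miRNAs lower in SS had a median GC content of 57.1%, against 42.9% for the miRNAs tested, and 10 of them start with U. Base composition is argued against as the whole cause, since the trend of sequences outside miRNA loci predicts 0.135 of their median change. Moved ends are argued against too, because with reads ending within 2 nt added the median change was 0.924 of that of exact reads, although miR773a kept 0.183 of its change and miR161.1 kept 0.375. Folding of the small RNA on itself stays open. The miRNAs called lower had a mean predicted free energy of -2.1 kcal/mol against -0.862 for the others (permutation p = 0.00147). Sequences outside miRNA loci that fold differed from unfolded ones by a median log2 change of -0.0916 ± 0.0298 (2 SD of bootstrap draws). That difference did not reach the larger decrease set beforehand as the sign of folding. It lies within its spread of the bound of -0.1, above which folding would have been argued against, so folding cannot be told apart from other causes.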
